A study of Mus musculus with 3 samples.

How the data were processed

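The samples were 3 sagittal sections of wild-type mouse embryos, 2 sections from 2 different embryos at E9.5 and 1 section from an embryo at E15.5, imaged by MERFISH, which reads RNA molecules in place through barcodes built up over rounds of fluorescence imaging. Per the labels, a design of 300 genes was hybridised on the Vizgen MERSCOPE platform. The deposited tables hold counts of 296 panel genes per segmented cell, and 4 genes of the design were sequential probes, which have no counts in these tables. The authors' tables also hold counts of 19 blank codes, which were given to no gene. Per the file headers, a second deposited table per section holds each cell's centre, volume and the summed intensity of the DAPI and PolyT stains. The deposited counts were whole numbers and the summed intensity values grew with cell volume. The header gives no unit for positions; they are read here as micrometres, the unit of MERSCOPE output. Segmentation and decoding settings are not given in the sources used here. The submitters' notes name Scanpy and Seurat, with no version or role.

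Cells with at least 10 counts of panel genes were kept, which left 830 of 1077 cells (77.1%) in E9.5 section 1, 6334 of 6835 (92.7%) in E9.5 section 2 and 195915 of 219525 (89.2%) in the E15.5 section. Kept cells held 68572, 1034730 and 21227345 counts. Blank codes made up 0.460%, 0.283% and 0.305% of all counts and stayed out of library sizes, clustering and tests. No doublet caller was run, since segmentation rather than droplets sets what counts as a cell; cells over 3 times the section's median volume were left out in an alternative. The stain intensities entered no comparison.

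Counts were scaled by depth and log-transformed, reduced to 30 principal components, joined in a graph of 15 nearest neighbours with Jaccard weights and clustered by the Leiden method (modularity) at a resolution of 1. The 2 E9.5 sections were clustered together and the E15.5 section on its own. Clusters are numbered from 1 by size. A cluster took the name of a cell class, written with the ending -like, where at least 3 panel markers of the class were at least 2-fold above all other kept cells on at least 20 counts, at least 2 of them stood among the cluster's top 10 genes by fold, and no other class had more markers there. The markers were fixed before the data were examined; this naming rule was set after the data had been seen. Endothelial-like cells were clustered again within each stage. A gene counted as raised in a subcluster at 2-fold or more over the other endothelial-like cells of that stage, and genes that define a cluster or subcluster are not findings.

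Cells are not replicates, so raw counts were summed per section. Stage was tested on sums over all kept cells and on sums over endothelial-like cells with edgeR's quasi-likelihood test and TMM factors, for genes with a summed count of at least 30. P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. With 1 section at E15.5 this test has 1 residual degree of freedom: it takes its spread from the 2 E9.5 sections and assumes that the lone section varies like them. The E9.5 sections were imaging regions 0 and 1 and the E15.5 section was imaging region 0. Imaging run was not modelled, and a difference of run between the stages could not be told apart from stage. Genes were therefore also counted by size alone, at least 2-fold in the same direction against each E9.5 section, with a floor of 3 counts per section. An exact permutation test over 3 sections cannot go below p = 0.333. Endothelial-like cells were compared with the other cells of the same sections on 6 sums with the section as a block, and the interaction of cell group and stage was tested on the same sums. The 6 endothelial markers name the class and are not counted in endothelial comparisons. Shares of cells carry exact Clopper-Pearson 95% intervals, and fold ratios of counts carry exact Poisson intervals; both cover counting error only.

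The neighbourhood of an endothelial-like cell was the most frequent cluster among its 20 nearest non-endothelial cells within 100 micrometres. A gene was called in a neighbourhood at 2-fold or more over the other endothelial-like cells of the section, with an interval that excludes 1 and at least 50 counts. A gene that the neighbouring cluster itself held at a higher share of counts was set apart, because counts can cross the drawn cell borders. Neighbourhoods were read at E15.5; at E9.5 no neighbourhood had 50 endothelial-like cells in each section.

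Gene lists were fixed before the data were examined. Those with at least 3 panel members were arterial, venous, lymphatic, capillary and tip, endocardial, brain endothelial, liver sinusoidal, lung endothelial, heart endothelial, Notch pathway, VEGF pathway, guidance and proliferation, with endothelial, macrophage, mural and mesenchyme markers. The other fixed lists had fewer members in the panel and are not reported. Named genes followed a rule also fixed then: for stage, up to 12 genes per direction with the largest smaller fold against the 2 E9.5 sections among the called genes; for endothelial-like against other cells, up to 12 per direction; for each neighbourhood of at least 200 endothelial-like cells, up to 3 genes by fold; and list members as examples. Other named genes are marked as chosen after their values were seen. Some results of single genes are not reported here.

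Alternatives were total-count and upper-quartile scaling, counts per cell volume, DESeq2 with its own size factors, no gene filter, other cell filters, subtraction of the blank level, a marker gate (at least 3 counts over at least 2 endothelial markers), a resolution of 0.5 or 2, other neighbourhood sizes and fold limits, no section block, and leaving out each section in turn. Added after the data had been seen were DESeq2 for the interaction, and the omission of E9.5 cells in 100-micrometre squares with under 0.5 times the section's share of Gnas. That fit was repeated with 1 spread shared by all genes, and the counts by size were repeated with total counts in place of TMM factors, both chosen after the results had been seen. The fits were tested on simulated data of the same size with 200 of 296 genes changed. At a dispersion of 0.1, stage over all cells called 82% of 4-fold and 33% of 2-fold changes, stage in endothelial-like cells called 75% and 24%, and endothelial-like against other cells called 96% and 45%. With no gene changed there were 0 calls, except 8 for stage in endothelial-like cells at that dispersion. The dispersion fitted to the real sums was 0.211 over all cells and 0.543 in endothelial-like cells, above the simulated one. The work used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.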

Results

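RNA molecules of 296 genes were counted in place in segmented cells of 2 E9.5 embryos, 1 section each, and of 1 E15.5 embryo. The panel was rich in genes of arteries, veins, lymphatic vessels, the endocardium and organ vessels, and the series title names endothelial heterogeneity in the embryo as its subject. E9.5 section 1 held 1077 cells and 69198 gene counts, E9.5 section 2 held 6835 cells and 1035999 counts, and the E15.5 section held 219525 cells and 21309070 counts. Kept cells had a median of 61, 128 and 84 counts and of 31, 53 and 36 genes in these 3 sections. H19, an imprinted non-coding RNA of fetal tissue, took the largest share of counts in each section, at 9.84%, 4.35% and 14.0%. A blank code averaged 16.4, 154 and 3385 counts in kept cells, and 40, 22 and 18 genes lay below the mean blank code of their section. The highest blank code held 47, 396 and 9671 counts over all cells, and 118, 71 and 81 genes lay below it. E15.5 has no replicate. Genes are identified by the symbols of the panel, without genome coordinates.

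Endothelial-like cells made up 2.77% of kept cells in E9.5 section 1 (23 cells, 95% interval 1.76 to 4.13%), 5.35% in E9.5 section 2 (339 cells, 4.81 to 5.94%) and 8.77% in the E15.5 section (17179 cells, 8.64 to 8.89%). At E9.5 they formed cluster 17, led by the Notch ligand Dll4, the tight junction gene Cldn5 and the connexin Gja4, and cluster 19, led by Cdh5, Pecam1 and Kdr. Cluster 17 held 190 cells, 23 of them in section 1, and all 172 cells of cluster 19 lay in section 2. Of the 23 cells in section 1, 18 lay in areas of low Gnas, described below. These 18 held 85 counts of Cldn5 but 0 of Pecam1, 0 of Cdh5 and 1 of Kdr, and the other 5 held 26, 3, 3 and 2. At E15.5 endothelial-like cells formed cluster 7 with 15339 cells, led by Pecam1 and Aplnr, and cluster 21 with 1840 cells, led by Cldn5, Rgs5 and the thyroid hormone transporter Slco1c1, which also ranked 2 mural markers among its top 10 genes. Other named classes at E15.5 were mesenchyme-like cells at 12.1% (11.99 to 12.28%), mural-like cells at 3.10% (3.02 to 3.18%) and macrophage-like cells at 1.08% (1.03 to 1.12%). The naming rule left 74.9% of E15.5 cells and 97.2% and 94.6% of the cells of the E9.5 sections unnamed. The order of the 3 endothelial shares rests on single sections and was not tested. Under the marker gate the shares were 1.57% in E9.5 section 1, 5.64% (5.08 to 6.23%) in section 2 and 6.04% (5.94 to 6.15%) at E15.5, and with no cell filter 1.21%, 5.22% and 5.39%. At a resolution of 0.5 they were 0.723%, 5.04% and 12.3%.

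**Figure D1:**
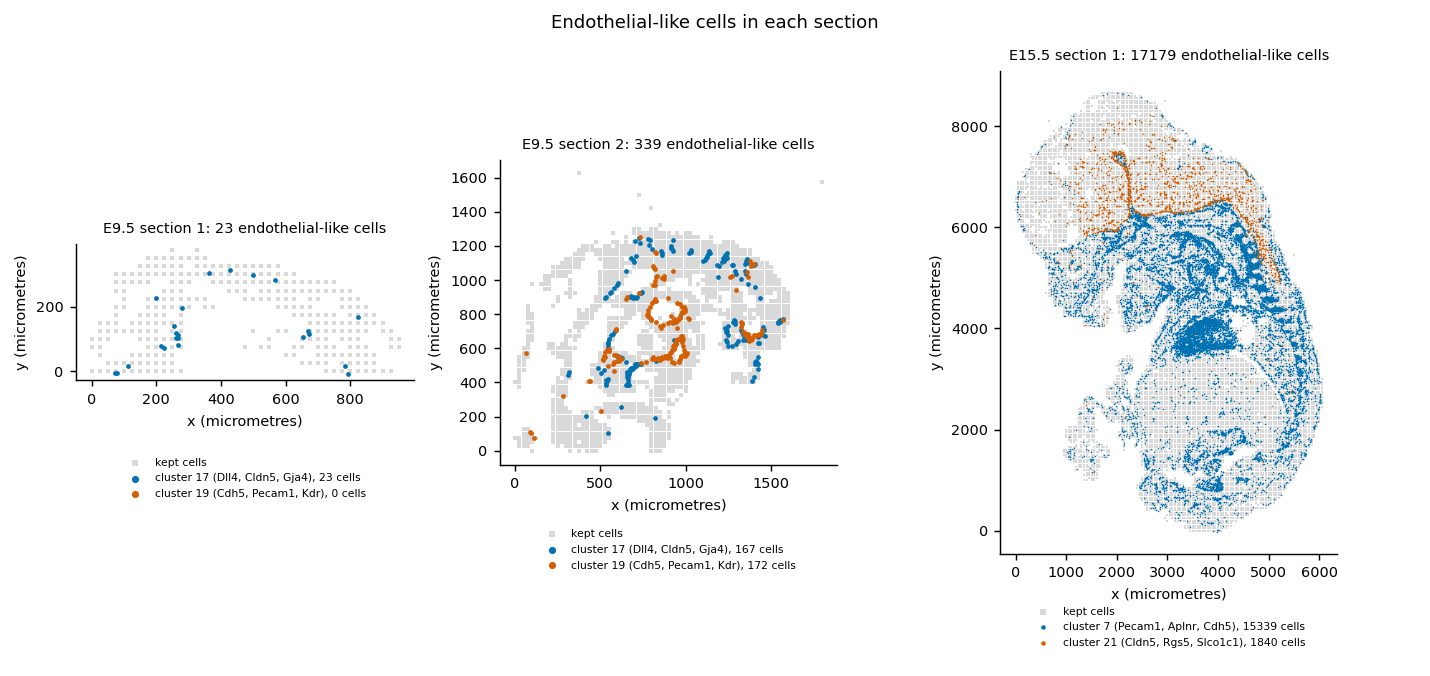
Positions of kept cells (grey) and endothelial-like cells (coloured by cluster) in each section, with x and y in micrometres on equal scales; the panels differ in size. The 23, 339 and 17179 endothelial-like cells spread through each section, and clusters 7 and 21 of the E15.5 section occupy different parts of it.

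Endothelial-like cells of E9.5 split into 7 subclusters. Subcluster 3 (55 cells, 15.2% of endothelial-like cells, interval 11.7 to 19.3%) was led by Gja5, an arterial connexin, at 76.8-fold over the other endothelial-like cells, and had 8 of 16 arterial list genes raised. Subcluster 4 (50 cells, 13.8%, 10.4 to 17.8%) also had 8 of 16 raised, among them Gja4 at 5.66-fold, the chemokine gene Cxcl12 at 3.71-fold and Dll4 at 3.27-fold. Subcluster 5 (49 cells, 13.5%, 10.2 to 17.5%) had 4 of 7 venous list genes raised, with Nrp2 at 6.71-fold and Nr2f2, a transcription factor of vein identity, at 4.92-fold. Subcluster 1 (77 cells, 21.3%, 17.2 to 25.9%) was led by Etv2, an ETS factor that starts the endothelial lineage, at 13.1-fold. Subcluster 2 (66 cells, 18.2%, 14.4 to 22.6%) was led by the adhesion receptor gene Adgrg6 at 8.43-fold, with Hand2 at 2.77-fold. Subcluster 7 (32 cells, 8.84%, 6.13 to 12.2%) was led by Ltbp4, Tbx20, Gata5 and Hand2, the last at 4.32-fold, and subcluster 6 (33 cells, 9.12%, 6.36 to 12.6%) by C1qa and H2afz, with Cdk1 at 3.50-fold. Section 1 gave 15 cells of subcluster 6, 5 of subcluster 1, 3 of subcluster 4 and 0 of the others. The split followed areas of the sections in which the broadly expressed gene Gnas was low: 75.3% of cluster 17 and 26.2% of cluster 19 lay in such areas, against 44.7% of all kept E9.5 cells. The shares were 72.7% for subcluster 1, 6.06% for subcluster 2, 50.9% for subcluster 3, 84% for subcluster 4, 26.5% for subcluster 5, 87.9% for subcluster 6 and 50% for subcluster 7.

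At E15.5 the endothelial-like cells split into 12 subclusters, and several followed 1 of the fixed lists. Subcluster 11 (679 cells, 3.95%, interval 3.67 to 4.25%) had all 5 lymphatic list genes raised, with Lyve1, a hyaluronan receptor of lymphatic vessels, at 26.03-fold and Prox1, the lymphatic fate factor, at 14.0-fold. It also raised 3 of 6 liver sinusoidal list genes and 1 macrophage marker, and 0 endothelial markers. Brain endothelial list genes led 2 subclusters, each with 9 of 10 raised. Subcluster 7 (1147 cells, 6.68%, 6.31 to 7.06%) held Spock2 at 25.3-fold and the lipid transporter gene Mfsd2a at 21.1-fold, but also Stmn2, a neuronal stathmin, at 24.9-fold and 5 raised mural markers. Subcluster 10 (786 cells, 4.58%, 4.27 to 4.90%) held the amino acid transporter genes Slc38a5 at 9.26-fold and Slc7a1 at 6.20-fold, and also raised 3 macrophage markers and 1 mural marker. Subcluster 2 (2753 cells, 16.0%, 15.48 to 16.58%) raised 3 of 5 capillary and tip list genes, with Gpihbp1, which anchors lipoprotein lipase in capillaries, at 4.03-fold beside Col15a1 at 8.27-fold. Subcluster 5 (1507 cells, 8.77%, 8.35 to 9.21%) raised 6 of 16 arterial list genes, with Jag1 at 4.21-fold and Gja4 at 4.10-fold, and 6 of 9 mural markers, with the smooth muscle myosin Myh11 at 15.45-fold. Subcluster 8 (923 cells, 5.37%, 5.04 to 5.72%) raised 4 of 5 endocardial list genes, with the natriuretic peptide receptor Npr3 at 6.24-fold. Subcluster 3 (2083 cells, 12.1%, 11.6 to 12.6%) was led by the cardiac transcription factors Tbx20 at 41.8-fold and Gata4 at 22.2-fold. The largest, subcluster 1 (2994 cells, 17.4%, 16.9 to 18.0%), was led by Foxd1 at 3.79-fold and Crabp1. The mesenchyme markers Col1a2 and Prrx1 were among its top 10 genes but under 2-fold, so 0 mesenchyme and 0 endothelial markers were raised. Subcluster 4 (1571 cells, 9.14%, 8.72 to 9.59%) was led by Foxf1, Stab2 and Spint2, with a median of 35 counts and 2 macrophage markers raised. Subcluster 6 (1249 cells, 7.27%, 6.89 to 7.67%) was led by Egfl8 and Adgrg6. Subclusters 9 and 12 had medians of 19 and 26 counts per cell, too few to describe. Of the 12, only subclusters 2, 7 and 10 raised any of the 6 endothelial markers, with 3, 2 and 2 raised. A count of 0 in the others is relative to the class and does not show that the markers were absent. The panel held 0 of the 18 cardiomyocyte markers fixed beforehand, so heart muscle cells could not be named or set apart.

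At E15.5 the genes of endothelial-like cells varied with the cells around them. There were 190 calls of a gene in a neighbourhood, over 98 genes and 20 neighbourhoods, and another 113 were set apart because the neighbouring cluster held the gene at a higher share. Beside clusters 3 and 4, led by neuronal genes such as Stmn2 and Tubb2b, 8 of the 27 called genes were on the brain endothelial list in each case, and mural markers such as Rgs5 and Vtn were among the others. Cluster 21, a part of the class, was formed on the same panel and led by Cldn5, Rgs5 and Slco1c1. It gave 1144 of the 1147 cells of subcluster 7, so calls of such genes are not independent of the clustering. Spock2 was 11.4-fold (10.89 to 11.98) and Mfsd2a 10.5-fold (9.83 to 11.2) over other endothelial-like cells beside cluster 3 (642 cells), and Slc7a5, a large neutral amino acid transporter, was 7.04-fold (6.57 to 7.54) beside cluster 4 (591 cells). Beside cluster 13 (1077 cells), which had the endothelial marker Cdh5 among its leading genes, Slc38a5 was 6.19-fold (5.56 to 6.89) and Cldn5 3.95-fold (3.81 to 4.09). Whether clusters outside the class hold endothelial cells was not tested. Stab2, a scavenger receptor of sinusoids, was 36.5-fold (30.2 to 43.8) in 386 cells, with a median of 32 counts, beside cluster 2, which was led by Car2 and Rgcc and had Stab2 itself among its leading genes. Beside the mesenchyme-like cluster 1 (5282 cells) Lyve1 was 4.58-fold (4.15 to 5.05), and beside the mural-like cluster 11 (615 cells) the Notch target Heyl was 2.21-fold (2.05 to 2.38). Tbx20 and Gata4 were 4.37-fold (4.16 to 4.60) and 4.14-fold (3.86 to 4.44) beside cluster 5, led by Htra1 and Bgn (4593 cells), and 7.75-fold (7.22 to 8.32) and 7.92-fold (7.17 to 8.74) beside cluster 19, a cluster of low counts (512 cells). Cluster 19 was led by Stab2 and had Clec4g and Oit3, also of the liver sinusoidal list, among its leading genes. Subcluster 3 of the endothelial-like cells, led by Tbx20 and Gata4, raised 0 endothelial markers. Whether its cells are endothelial was not tested. Egfl8 was 6.98-fold (5.92 to 8.18) beside cluster 22, led by Scn7a and Rgs4 (311 cells). No gene was called for endothelial-like cells beside cluster 6 (1334 cells), where all 4 genes past the limits were set apart. The folds come from 1 section and have no test between embryos. The median distance to the nearest non-endothelial centre was 8.86 micrometres, and without the 38.9% of cells that had one within 8 micrometres the calls numbered 136, with 122 of the 190 among them. Under the marker gate the calls numbered 175, but 91 of the 190 were among them and 261 were set apart.

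**Figure D2:**
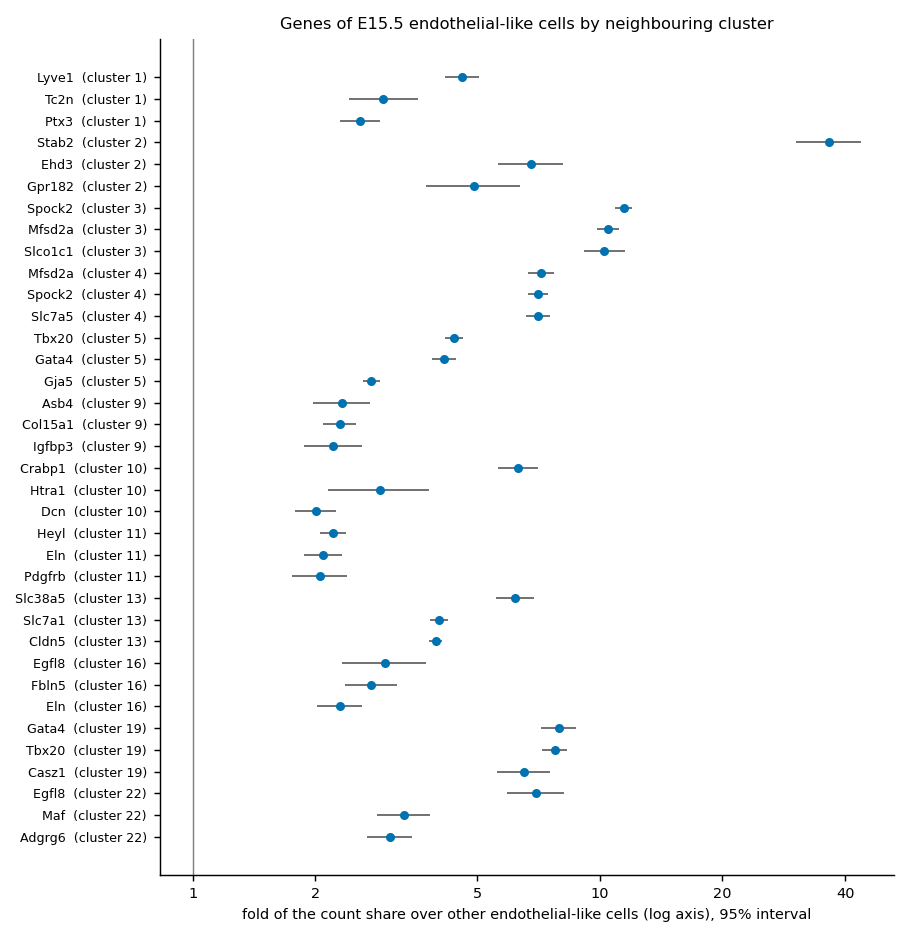
Fold of each named gene's share of counts (log axis) in E15.5 endothelial-like cells of a neighbourhood over the other endothelial-like cells of the section, with exact 95% intervals as bars. Stab2 beside cluster 2 lies farthest out, at 36.5-fold, and brain endothelial list genes beside clusters 3 and 4 lie between 7.04 and 11.4.

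Between stages, over all kept cells, Stmn2 and Tubb2b rose most and Lin28a and Prtg fell most. The sums cover whatever cells each section held. A change in cell make-up therefore cannot be told apart from a change within cells. Stmn2 rose by 5.36 ± 0.63 (log2, SE), from 694 ± 173 CPM, counts scaled by TMM to a common depth (SD, n = 2), to 28222, and the neuronal beta-tubulin Tubb2b rose by 4.09 ± 0.68, from 820 ± 75.5 to 13946. The adjusted p-values (edgeR quasi-likelihood, Benjamini-Hochberg) were 2.04e-13 and 4.25e-07, and both genes were higher than in each of the 2 E9.5 sections. Fabp7, a fatty acid binding protein of radial glia, rose by 3.80 ± 1.01, Scn3a, a sodium channel of the embryonic brain, by 3.74 ± 1.03, and Cytl1, a secreted protein of cartilage, by 3.82 ± 1.03. Lower were Prtg, a receptor of the early neural tube and mesoderm, at -5.83 ± 0.74 (39434 ± 11215 to 694 CPM), and Lin28a, an RNA-binding protein that blocks let-7 maturation, at -6.05 ± 0.84 (15016 ± 5993 to 227). Their adjusted p-values in the edgeR quasi-likelihood test were 1.31e-11 and 4.25e-10, again in the same direction against both E9.5 sections. These values rest on 1 spread that the fit shared among all genes. Without E9.5 areas of low Gnas the fit did not share it fully, and the adjusted p-values (edgeR) were 0.00815 for Stmn2, 0.0442 for Tubb2b and 0.0120 for both Prtg and Lin28a.

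In all, 28 genes rose and 16 fell among 296 tested, and 48 were higher and 45 lower by size alone. Also named among the genes that rose were Klf4, Lox, which cross-links collagen and elastin, Mgp, an inhibitor of calcification, Fibin, Maf, Adgrg6 and Rgs4, with log2 changes from 2.61 to 3.08 and adjusted p-values (edgeR) from 0.0264 to 0.0463. The other named genes that fell were the carbonic anhydrase Car14, the pericyte gene Higd1b, the glucose transporter Slc2a1, Slc45a3, the mitotic genes Pimreg and Aurka, Etv2, Tmem108, the basement membrane collagen Col18a1 and the venous ephrin receptor Ephb4, with log2 changes from -4.03 to -1.96 and adjusted p-values (edgeR) from 0.00754 to 0.0463. Ephb4 was 3.85 times lower than in section 1 and 3.94 times lower than in section 2. These 24 named genes kept their sign under every scaling tried, but not all stayed called. Ephb4, Aurka, Col18a1, Pimreg, Etv2, Tmem108 and Slc45a3 were not called with upper-quartile scaling, while the named genes that rose were. Per cell volume, Etv2 alone stayed called among the named genes that fell, and Stmn2, Cytl1, Scn3a, Fabp7 and Mgp among those that rose. Of the 28 genes that rose, 10 had fewer counts than the mean blank code in an E9.5 section, among them the named genes Cytl1, Fabp7, Scn3a, Mgp and Adgrg6, as Etv2 and Slc45a3 had at E15.5. The highest blank code of each section held more, at 47, 396 and 9671 counts. Klf4, Lox, Maf and Rgs4 also lay below it in an E9.5 section, and Lin28a, Slc2a1, Car14 and Higd1b at E15.5. Gata4, chosen after its values were seen, fell in the test although it was 2.34-fold higher than in section 1, where it had 19 counts. The counts were 22 higher and 5 lower with upper-quartile scaling, which moved the median of all genes by 0.26 on the log2 scale, 10 and 1 with counts per cell volume, where Stmn2 was called but Tubb2b, Prtg and Lin28a were not, 15 and 16 after subtracting the blank level, and 46 and 46 with DESeq2. Leaving out E9.5 cells in areas with low Gnas left Stmn2 and Tubb2b higher and Lin28a and Prtg lower (2 and 2), with the sign of all 44 genes kept, and with 1 spread shared by all genes that omission gave 26 and 18. By size alone, leaving out section 1 gave 67 higher and 69 lower genes and leaving out section 2 gave 77 and 73, with 1 comparison fewer to pass.

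**Figure D3:**
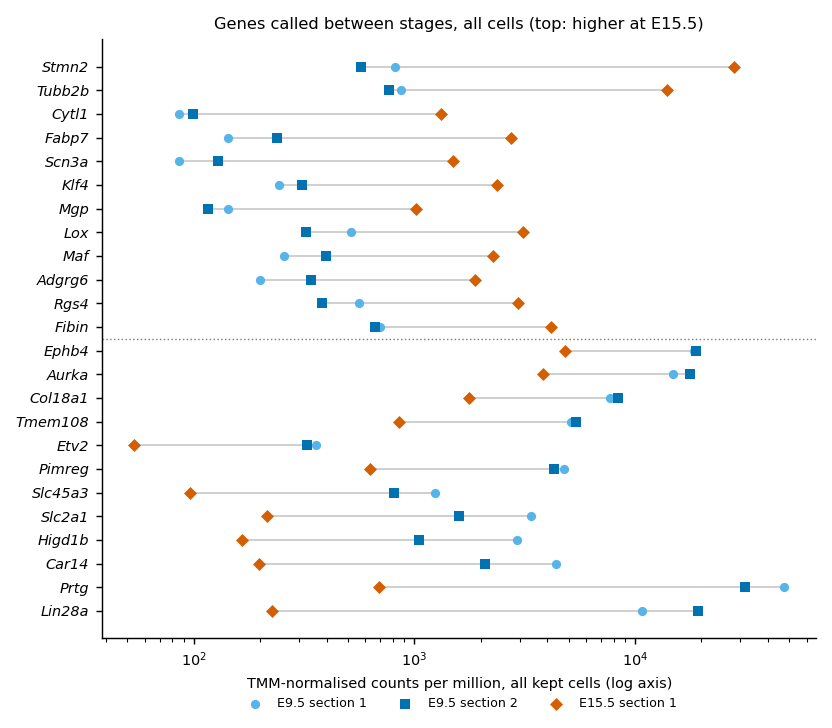
TMM-normalised CPM (log axis) of the 24 named genes over all kept cells, 1 symbol per section. The E15.5 section lies to the right of both E9.5 sections for the 12 genes that rose and to the left for the 12 that fell, from 28222 for Stmn2 to 53.8 for Etv2.

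Single members of the vessel lists were called, and no list was tested as a whole. Of 16 arterial genes Mgp rose and Notch1 fell, of 7 venous genes Ephb4 fell, of 5 capillary and tip genes Gpihbp1 rose, and of 5 endocardial genes Adgrg6 rose and Gata4 fell. Of 10 brain endothelial genes Spock2 and Itm2a rose and Slc2a1 fell, of 6 liver sinusoidal genes Maf and Clec4g rose, of 4 lung endothelial genes Fibin rose, and of 3 heart endothelial genes Fabp4 rose. Of 5 Notch pathway genes Notch1 fell and of 3 guidance genes Ephb4 fell. DESeq2 called other numbers in some of these lists: 1 higher and 4 lower arterial, 1 higher and 1 lower venous, 2 higher capillary and tip, 3 higher and 1 lower brain, 2 higher and 1 lower liver, 0 higher and 1 lower heart, and 2 lower guidance genes. In the endocardial list DESeq2 called Hand2 lower and did not call Gata4. Clec4g, Fabp4 and Gpihbp1, like the macrophage marker Tyrobp, had fewer counts than the mean blank code in both E9.5 sections, and these 4, Maf, Adgrg6 and Etv2 were not called after subtracting the blank level. Adjusted over the list alone the counts were the same, except that Tcf15 fell too in the heart endothelial list and Unc5b in the guidance list. In edgeR, 0 of 5 lymphatic genes changed (1 higher at an unadjusted p under 0.05, 1 by DESeq2), 0 of 3 VEGF pathway genes (1 higher unadjusted, and 1 higher and 1 lower by DESeq2), and 0 of 6 proliferation genes (3 lower unadjusted, 3 by DESeq2), with the same 0 adjusted over the list alone. Among cell type markers Etv2 fell of 6 endothelial genes, Tyrobp rose of 7 macrophage genes, Higd1b fell of 9 mural genes and Dcn rose of 4 mesenchyme genes. Adjusted over the list alone these counts were 1, 2, 1 and 1. These sums cover all cells of a section, so a list's change is not one of endothelial cells. Every list call over all genes ended when E9.5 areas with low Gnas were left out, but with 1 spread shared by all genes Mgp, Adgrg6, Spock2, Itm2a, Maf, Fibin, Dcn, Slc2a1, Gata4 and Etv2 were called there, so for these the end of the call rests on the spread. Spock2 went from 2.46 to 3.21, Fibin from 2.61 to 2.80, Maf from 2.76 to 2.61, Etv2 from -2.66 to -2.38 and Slc2a1 from -3.54 to -3.17 (log2), but Notch1 from -2.29 to -1.16, Higd1b from -3.58 to -2.12, Gpihbp1 from 1.77 to 1.22 and Fabp4 from 1.74 to 1.08. Notch1, Gpihbp1, Fabp4 and Clec4g were then neither higher nor lower by size, and Gata4 was neither before or after that omission.

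Within endothelial-like cells, the question of the series title, no gene passed the edgeR test between stages: 0 of 290 rose and 0 fell, against 24 higher and 0 lower at an unadjusted p under 0.05, and 0 and 1 by DESeq2 (Prtg, chosen after its values were seen). By size alone 37 genes were higher and 20 lower at E15.5. Of the brain endothelial list 4 were higher by size: Spock2 was at least 3.65-fold above section 1, where it had 0 counts, and 13.5-fold above section 2, Itm2a at least 7.72-fold and 3.11-fold, and Slc7a5 and Mfsd2a, each with 1 count in section 1, 4.59-fold and 3.45-fold above section 2. These folds are lifted by the TMM factors of 1.42 in section 1 and 0.831 at E15.5. With total counts Slc7a5 was at least 1.45-fold and Mfsd2a at least 1.23-fold above section 1, and 2 of the list, Spock2 and Itm2a, were higher by size. Nrp2, a venous and VEGF pathway list gene, was at least 4.07-fold above section 1 and 5.79-fold above section 2. Arterial list genes went both ways, with Jag1 (1 count in section 1) 2.48-fold and Cxcl12 (2 counts) 4.25-fold above section 2, and Notch1 3.15 and 2.80 times, Acvrl1 3.07 and 3.64 times and Sema3g 2.06 and 3.38 times below sections 1 and 2. Ephb4 was 6.75 and 4.68 times lower, and of 6 proliferation genes Cdk1 was 3.29 and 2.33 times and Birc5 4.06 and 2.49 times lower. Against section 1 the same TMM factors lift the rise of every gene, Nrp2 and Rgs5 included, and lessen every fall. Of 9 mural markers 3 were higher by size, Acta2, Vtn and Rgs5, the last at least 5.39-fold and 14.3-fold, and with total counts this held for 1 of them, Rgs5. The 2 mesenchyme markers Col1a2 and Dcn were also higher by size. Over all genes, edgeR and DESeq2 called 0 members of every list, with 0 to 2 per list at an unadjusted p under 0.05. Adjusted over the list alone 1 arterial gene (Mgp), 2 liver sinusoidal genes (Dnase1l3 and Clec4g) and 1 macrophage gene (Tyrobp) passed as higher, all of them at 0 counts in section 1, and 0 genes of the other lists passed.

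The endothelial-like sum of section 1 held 23 cells and 1561 counts, against 64410 in section 2 and 1779824 at E15.5. The 23 cells held few counts of Pecam1, Cdh5 and Kdr, so folds against section 1 compare with cells that few endothelial markers identify. By size, leaving out section 1 gave 101 higher and 57 lower genes and leaving out section 2 gave 58 and 41, with 1 comparison fewer to pass. Total counts in place of TMM gave 20 and 29. A resolution of 0.5, which left 6 cells in section 1, called 34 higher and 7 lower. The marker gate called 1 gene higher, and leaving out areas of low Gnas called 2 higher, among them Tyrobp, chosen after its values were seen. Without those areas section 1 held 5 endothelial-like cells and 352 counts, and 14 genes were higher and 3 lower by size. Of the genes named above by size, Itm2a, Cxcl12, Sema3g, Rgs5, Col1a2 and Dcn were among them, and Spock2, Slc7a5, Mfsd2a, Nrp2, Jag1, Notch1, Acvrl1, Ephb4, Cdk1, Birc5, Acta2 and Vtn were not.

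Compared with the other cells of the same sections, endothelial-like cells held more of Dll4, the Notch ligand of arteries and tip cells, and of Aplnr, the apelin receptor. Dll4 was 14.8-fold, 39.7-fold and 6.89-fold higher in E9.5 sections 1 and 2 and the E15.5 section (log2 4.00 ± 0.76, SE, adjusted p = 0.0320, edgeR quasi-likelihood, Benjamini-Hochberg), with 4 counts in section 1. Aplnr was 9.25-fold, 10.1-fold and 11.2-fold higher (log2 3.35 ± 0.54, adjusted p = 0.0159, edgeR), so both were higher in 3 of 3 sections. They were the 2 genes called higher of 290, and 0 were called lower by edgeR, against 17 and 15 at an unadjusted p under 0.05 and 17 and 14 by DESeq2. Dll4 belongs to the arterial and Notch lists and Aplnr to the venous list. Adjusted over the list alone, 4 of 16 arterial, 1 of 7 venous, 2 of 5 Notch and 1 of 3 guidance genes were higher, and the 1 VEGF gene that passed was Kdr, a marker that names the class and is not counted. The class was made by clustering on the same genes, and Dll4 and Aplnr were each among the 10 leading genes of 3 of its 4 clusters. The test therefore describes the class and is no independent evidence for these genes. The 2 genes were called with total counts, DESeq2, no gene filter, the marker gate, resolutions of 0.5 and 2, low-Gnas areas left out and each section left out, but not without a section block, which called 0. Upper-quartile and per-volume scaling, blank subtraction and other cell filters were not run for this comparison. Leaving out section 1 gave 18 higher and 2 lower genes, leaving out section 2 gave 5 and 0, and leaving out the E15.5 section gave 7 and 3.

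Whether the stage difference of a gene in endothelial-like cells differed from that in the other cells was tested by the interaction in edgeR, which called 0 genes higher and 0 lower, against 18 and 1 at an unadjusted p under 0.05. DESeq2 called 2 higher, the contractile gene Acta2 and Rgs5, and 2 lower, Pcdh17 and Stmn2, all chosen after their values were seen.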

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

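The interaction test named here was chosen before the data were examined; the comparison with chance was added after these values had been seen. In 3 list genes the difference between endothelial-like and other cells lay on opposite sides at the 2 stages. Pdgfrb, a receptor of pericytes, was 2.07-fold higher in endothelial-like cells at E15.5, against 0.939-fold and 0.397-fold in E9.5 sections 1 and 2, with 7 counts in section 1. Slc2a1, the glucose transporter of the brain endothelial list, was 1.90-fold higher at E15.5, against 0.558-fold and 0.445-fold at E9.5, with 5 counts in section 1. Slc7a1, a cationic amino acid transporter of the same list, was 1.56-fold higher at E15.5, against 0.306-fold and 0.799-fold at E9.5, with 7 counts in section 1. The interaction of cell group and stage did not call them (adjusted p = 0.912, 0.912 and 0.968, edgeR quasi-likelihood, Benjamini-Hochberg). Of 34 list genes with a direction in all 3 sections, 3 parted this way, as did 17 of all 104 such genes (16.3%). By chance 25% of sign patterns would do so if the 3 directions were independent. Sections share differences between cell groups, so the 25% cannot decide whether the 3 genes parted by chance. No explanation was tested for these genes.

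Blank codes, which belong to no gene, held 320 counts in E9.5 section 1, 2943 in E9.5 section 2 and 65129 in the E15.5 section. They entered no main comparison, and served as a noise level that 1 alternative subtracted. They were 0.460%, 0.283% and 0.305% of all counts.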

How the results depend on the processing

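Chosen only after the data had been seen were the omission of E9.5 areas with low Gnas, with or without 1 spread shared by all genes, total counts for the counts by size and DESeq2 for the interaction, 18 of 109 alternatives over 16 results. In 59 alternatives a count stayed within 1.5 times, or a share within its interval, of the reported value. In 50 it moved, as listed below; the cause was not tested except where it is given. Stage over all cells (28 higher, 16 lower) gave 46 and 46 genes with DESeq2, 15 higher after subtracting the blank level, 5 lower with upper-quartile scaling, 10 and 1 per cell volume, and 2 and 2 without areas of low Gnas. There all 44 genes kept their sign, 22 of 28 stayed higher and 14 of 16 were lower by size. Gata4, among the 16, had not been lower by size before the omission. The median SE went from 0.844 to 0.723. The common dispersion went from 0.211 to 0.232 and the median prior degrees of freedom from infinite to 5.07. With 1 spread shared by all genes that omission gave 26 and 18, with 23 of the 28 and 12 of the 16 called again, so most calls ended because the spread was no longer shared. Lox, no longer called, went from 2.91 ± 0.96 to 3.10 ± 0.72 (log2, SE), and Ephb4 from -1.96 ± 0.63 to -1.41 ± 0.55. By size (48 and 45), leaving out 1 E9.5 section gave 67 to 77 higher and 69 to 73 lower. That drops 1 of the 2 comparisons a gene must pass, so counts by size can only stay or grow, in endothelial-like cells too. Stage in endothelial-like cells (0 and 0) had 0 calls in 19 of 24 alternatives. DESeq2 called 1 lower, the marker gate 1 higher, a resolution of 0.5 called 34 and 7 with 6 cells in section 1, and the omission of low-Gnas areas, with 5 cells in section 1, 2 higher. By size (37 and 20) that omission gave 14 and 3, total counts 20 higher, and leaving out 1 E9.5 section 58 to 101 higher and 41 to 57 lower. In these cells total-count, upper-quartile and per-volume scaling moved the median of all genes by -0.20, -0.18 and -0.56 on the log2 scale. The interaction (0 and 0) had 2 and 2 calls with DESeq2. Endothelial-like against other cells (2 and 0) gave 11 and 4 with total counts, 17 and 14 with DESeq2, 0 higher without the section block, 7 higher with the gate, 10 and 1 at a resolution of 0.5, 11 and 2 at 2, and 5 to 18 higher and 0 to 3 lower leaving out 1 section. The endothelial share of E9.5 section 1 (2.77%) was 1.57% by the gate, 0.723% at a resolution of 0.5 and 1.21% by the gate with no cell filter. That of E15.5 (8.77%) was 6.04%, 12.3% and 5.39% in turn, 8.28% at a resolution of 2 and 8.93% in cells of at least 30 counts. That of E9.5 section 2 (5.35%) stayed, with 5.64% by the gate and 5.22% by the gate with no cell filter. Neighbourhood calls (190) numbered 315 at a limit of 1.5-fold and 94 at 3-fold, as a lower or higher limit must give more or fewer. The gate kept their number (175) but 91 of the 190 recurred, and 261 were set apart. Depth limits E9.5 section 1 most, with 68572 counts in all and 1561 in endothelial-like cells. No paired analysis was possible because each section comes from its own embryo and the stages share fewer than 2 replicate numbers; this concerns the stages, as cell groups were compared within sections with the section as a block.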

Other observations

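Of the tests in this part, those of unread codes, of fewer counts, of brain endothelial list genes crossing borders and of counts from surrounding cells were chosen only after the results had been seen. Several E15.5 clusters outside the endothelial-like ones were led by genes with a known place in the embryo. Macrophage-like cluster 18 (2107 cells) was led by the scavenger receptor Mrc1, F13a1 and the complement genes C1qb and C1qc, and also by Lyve1, the gene that led the lymphatic list among endothelial-like cells. Cluster 8 (12043 cells) was led by the cartilage gene Cytl1 and by Mgp, cluster 17 (2772 cells) by Fabp7 and the glutamate transporter Slc1a3, and cluster 6 (15621 cells) by Pdlim3 and Acta2. At E9.5, cluster 6 (392 cells) was led by Acta2, Pdlim3 and Tbx20, cluster 3 (586 cells) by Tcf15, a transcription factor of paraxial mesoderm, and cluster 8 (331 cells) by Fabp7. Genes that lead a cluster define it, so these are descriptions and not differences found by a test. At E15.5, 7 clusters led by Scgb3a1 with Fam89a or Cfl1 held 10362 cells (5.29%), with medians of 12 to 24 counts and 0.564 to 1.24% blank counts, against 0.200 to 0.928% in the other clusters.

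Further neighbourhoods of E15.5 endothelial-like cells had called genes of their own. Beside cluster 10, led by Wnt4 and Spint2 (328 cells), Crabp1 was 6.30-fold (5.62 to 7.05) and Htra1 2.88-fold (2.14 to 3.80) over other endothelial-like cells. Beside cluster 16, led by Hand2 and Rgs4 (273 cells), Egfl8 was 2.97-fold (2.32 to 3.74) and the elastic fibre genes Fbln5 and Eln 2.74-fold (2.36 to 3.17) and 2.30-fold (2.02 to 2.60). Beside cluster 9, led by Prrx1 and Prrx2 (582 cells), Asb4 was 2.33-fold (1.97 to 2.73) and Col15a1 2.30-fold (2.09 to 2.52). Beside cluster 22 the transcription factor Maf was 3.30-fold (2.83 to 3.83) and Adgrg6 3.05-fold (2.68 to 3.45).

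In E9.5 section 2, the 170 endothelial-like cells in areas of low Gnas held less Pecam1, Cdh5 and Kdr (30.6, 52.9 and 33.9 per 10000 counts) than the 169 others (96.1, 208 and 109), and more Cldn5 (329 against 127). Fewer counts per cell are argued against as the whole explanation, since the mean over all genes was 0.753 (bootstrap 95% interval 0.645 to 0.882) of that in the others, against 0.214 for the 3 genes. A candidate explanation is that part of the codes was not read in these areas: over 108 squares of 100 micrometres the lowest correlation among the proliferation genes, which dividing cells share, was r = -0.591 (Cdk1 and Cenpf), against 0.223 over 2713 squares at E15.5. That vessels outside the heart hold little of these 3 genes stays open, because gated cells away from the Acta2-led cluster held them outside the areas at 3.87 (3.36 to 4.47) times their share inside, between the bounds of 2 and 4 set before the test. Other cells of these areas shifted too. In section 2 they held less H19 (129 against 594 per 10000 counts) and Cenpf (15.8 against 63.0), and more Cdk1 (73.6 against 36.0). In section 1 they held less H19 (17.8 against 1598) and Cenpf (7.27 against 62.3), and more Cdk1 (99.3 against 38.8). A difference between vessels alone does not account for these other cells. For the 3 genes in endothelial-like cells, a real difference between vessels still cannot be told apart from unread codes.

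Beside clusters 3 and 4 of the E15.5 section, brain endothelial list genes were high in endothelial-like cells together with the neuronal genes Stmn2 and Tubb2b. Counts crossing cell borders are argued against for the list genes, since in 100% of their calls (16 of 16, set-apart genes included) the endothelial-like cells held a higher share than the neighbouring cluster. For Stmn2 and Tubb2b, which the neighbouring clusters held at a higher share, that source stays open: their share was 1.22 (1.17 to 1.27) times higher in 682 cells with a non-endothelial centre within 8 micrometres than in 551 others, between the bounds of 1.1 and 1.5 set before the test. The same ratio was 1.12 (1.07 to 1.18) for Mfsd2a, Slco1c1 and Slc7a5. Brain vessels of their own kind remain an untested biological explanation, as the labels name no organs.

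Of the 37 genes higher by size at E15.5 in endothelial-like cells, 14 were held at a higher share by the other cells of that section, among them Stmn2, Tubb2b, Col1a2, Dcn, Spock2 and Itm2a. Counts from surrounding cells may have added to these, but 14 of 37 lies between the bounds set for the test, so that source stays open. Of the 37, Epas1 (96.5 against at most 79.0 per 10000 counts in any other cluster) and Rgs5 (60.7 against at most 37.8) stood above every other cluster of the section. Rgs5 is a mural marker. Other mural markers were also higher in endothelial-like than in other E15.5 cells, with Foxs1 at 3.71-fold, Kcnj8 at 3.33-fold, Vtn at 2.63-fold, Abcc9 at 2.23-fold and Pdgfrb at 2.07-fold. Whether the class holds mural cells was not tested, so differences in these markers cannot be given to endothelial cells alone. The stage itself, with 1 embryo at E15.5, stays open as the biological explanation and was not tested apart from the section.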
